A study of Homo sapiens with 6 samples.

How the data were processed

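Chromatin of Pfeiffer, WSU-DLCL2 and KARPAS-422 cells was fixed with formaldehyde and immunoprecipitated with an antibody against H3K27me3, per the labels' protocols. Each line had 1 H3K27me3 library and 1 input library. The lists of enriched intervals, called islands, were analysed here for the 3 lines; wild-type lines named in the title of the series were not analysed here. Reads were aligned with Bowtie to hg19 and islands were called with SICER, per the submitters' processing notes, which as used here give no versions. The names of the deposited lists give a window of 750 bases, a gap of 2250 bases and a false discovery rate of 0.001. Read filters and the handling of duplicate reads are not given in the sources used here.

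Each deposited list gives, per island, whole counts of H3K27me3 reads and of input reads, a p-value, a fold over input and a false discovery rate (q-value), all made by the authors. The fold is the ratio of the H3K27me3 and input counts after scaling the libraries, and the files' values returned 1 scaling per list: an H3K27me3 to input library ratio of 1.16 in Pfeiffer, 1.27 in WSU-DLCL2 and 1.65 in KARPAS-422. The number of intervals tested, recovered from the p-values and false discovery rates, was 24390, 28245 and 33457, of which 87.4%, 82.1% and 85.1% are listed. The lists name islands only, so the full depth of the libraries is unknown and reads outside islands were not used here. Folds were used to describe, rank or filter islands within a list. Where folds, or lists filtered by fold, are set side by side between lines, each fold rests on that line's own libraries and scaling. Positions were counted from 0 with an inclusive end in the files and are printed counted from 1.

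Lists held 21320, 23180 and 28472 islands. Chromosome X, and any other sequence outside the 22 autosomes, was left out of the comparisons. Covered bases were counted on the grid of 750 bases and divided by the autosomal length of 2879 Mb, taken as the last listed base of each chromosome. Overlap of 2 lists was the Jaccard index, set beside 1000 circular shifts of 1 list as a description. An island counted as shared with at least 1 base of overlap. Intervals of folds are 95% intervals for the ratio of 2 counts, exact for counting error only. In 2000 simulated draws, made without selecting ratios by size, they held the true ratio in 96.9%. Relations with gene density used permutation tests with 100000 resamples and protein-coding genes per chromosome of the RefSeq table for GRCh38.p14, of which no coordinates were used because the islands are on hg19.

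Input reads per kb of islands were used as a stand-in for DNA copy number along the genome. Other influences on input reads were not separated from it. For each 1 Mb bin they were pooled over islands centred within the bin and 2 Mb to either side (at least 30 kb of islands) and divided by the autosomal median of the line. A bin was called balanced where all 3 lines lay between 0.85 and 1.15. A change in copy number shorter than this window can be missed, and input read inside single bins, where both lines had at least 30 kb of islands, does not reach stretches without islands. The bins, the balanced class and the runs of at least 5 bins with an input of 0.75 or less, or of 1.3 or more, were chosen after the data had been seen.

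The comparisons, the alternatives and the rule for named intervals were otherwise set before the data were examined. The rule took 12 islands in all 3 lines, 6 per line alone with at least 50 H3K27me3 reads and no other line's island within 10 kb, and 4 per pair of lines, each by fold percentile within its own list. No hg19 annotation was used here, so intervals are named by position, and the planned results on promoters and on 14 gene lists were not run. Alternatives were a false discovery rate of 1e-10, a fold of at least 2, chromosome X included, lists of equal number or equal covered length, other overlap and length minimums, and islands under 5 kb apart joined. Those added later were balanced bins only, shifts of 0.5 to 2 Mb, and lists without islands of over 3 times the median input reads per kb. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.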

Results

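H3K27me3, the repressive histone mark deposited by the methyltransferase EZH2, was mapped by chromatin immunoprecipitation and sequencing in 3 cell lines of diffuse large B cell lymphoma. Pfeiffer, WSU-DLCL2 and KARPAS-422 all carry mutant EZH2 according to the labels. The labels give them average gIC50 values of 28, 134 and 232 nM, without naming the compound or giving gIC50 in full, and the lines are named in that order throughout. The study set out to profile lines that differ in their sensitivity to GSK126, an EZH2 inhibitor. Each line had 1 immunoprecipitated library and 1 input library, so no difference between lines could be set against a replicate spread and no p-value between lines was computed. The deposited lists held 17024803 H3K27me3 reads in autosomal islands in Pfeiffer, 17188115 in WSU-DLCL2 and 16039824 in KARPAS-422. The input reads in the same islands were 8800268, 8224578 and 5694645, so fold values rest on fewest input reads in KARPAS-422.

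The mark covered nearly the same share of the autosomes in the 3 lines but was divided differently. Islands covered 738 Mb in Pfeiffer, 714 Mb in WSU-DLCL2 and 712 Mb in KARPAS-422, or 25.6%, 24.8% and 24.7% of the autosomal length. Pfeiffer had 21258 islands with a median length of 20.25 kb (quartiles 12.75 and 38.25 kb). WSU-DLCL2 had 23066 islands with a median of 18.75 kb (quartiles 11.25 and 35.25 kb). KARPAS-422 had 27589 islands with a median of 15.75 kb (quartiles 9.75 and 28.5 kb). Median island length and island number thus followed the order of the gIC50 values, but 3 lines are too few for a correlation. Covered length did so only without chromosome X, with which it was 738.7, 715.1 and 726.3 Mb. The median fold over input, as the authors' files give it, was 1.58, 1.54 and 1.61. A fold of at least 2 was reached by 10.5% of the islands in Pfeiffer, 11.3% in WSU-DLCL2 and 19.6% in KARPAS-422. With only these islands KARPAS-422 covered 179 Mb, Pfeiffer 104 Mb and WSU-DLCL2 98.2 Mb.

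Long islands were fewest in KARPAS-422, though this depends on the list used. Islands of at least 50 kb numbered 3725 in Pfeiffer, 3644 in WSU-DLCL2 and 3060 in KARPAS-422, and held 52.9%, 48.6% and 41.3% of the covered bases. Among islands with a fold of at least 2 the order was the opposite, with 613, 620 and 1034 islands of that length. A fixed fold may not select alike in each line, since folds were lower in some runs of raised input. On chromosome 5 from 52000001 to 90000000 the median was 1.33 in Pfeiffer, against 1.45 and 1.47. Such runs held 374 bins in Pfeiffer, 188 in WSU-DLCL2 and 205 in KARPAS-422. With islands under 5 kb apart joined, WSU-DLCL2 had the most (4305, against 4130 in Pfeiffer and 3884 in KARPAS-422). Islands of 100 kb or more had a higher median fold than islands of 5 to 20 kb in each line (1.78 against 1.55 in Pfeiffer, 1.76 against 1.51 in WSU-DLCL2 and 1.92 against 1.58 in KARPAS-422). Fold did not rise steadily with length, since the few islands under 5 kb (328, 645 and 1156) had the highest medians of all length classes (1.93, 1.81 and 1.99). The longest island of Pfeiffer lay on chromosome 17 from 46203001 to 46918500 (715.5 kb, fold 1.75). That of WSU-DLCL2 lay on chromosome 7 from 28297501 to 28945500 (648 kb, fold 1.56). In KARPAS-422 an island of 905.25 kb on chromosome 20, from 59612251 to 60517500, had a fold of 2.47. An island of nearly the same length on chromosome 11, from 110574001 to 111478500, had a fold of 1.19 and 5.51 times the median input reads per kb.

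Most covered bases of each line were also covered in each other line. The Jaccard index, the shared bases divided by the bases covered in either line, was 0.576 for Pfeiffer and WSU-DLCL2. It was 0.555 for Pfeiffer and KARPAS-422 and 0.553 for WSU-DLCL2 and KARPAS-422. Shifting 1 list along each chromosome gave medians of 0.153, 0.155 and 0.151, and the highest of 1000 shifts were 0.178, 0.190 and 0.180. Another 200 shifts, of only 0.5 to 2 Mb and by the same distance on every chromosome, keep regional clustering. They gave higher medians of 0.232, 0.235 and 0.229, with highest values of 0.263, 0.265 and 0.254. The 1000 shifts drew a separate distance for each chromosome, so the highest values of both sets are not directly comparable. Of the 1033 Mb covered in any line, 41.2% was covered in all 3 lines, 27.1% in 2 and 31.8% in 1. The index of Pfeiffer and WSU-DLCL2 exceeded that of Pfeiffer and KARPAS-422 on 15 of 22 chromosomes. It exceeded that of WSU-DLCL2 and KARPAS-422 on 15 of 22 as well, counted separately. Its lead was lost among islands with a fold of at least 2, where Pfeiffer and KARPAS-422 had 0.345 and Pfeiffer and WSU-DLCL2 0.283. At that fold WSU-DLCL2 and KARPAS-422 had 0.278, and only 15.1% of the covered bases were covered in all 3 lines.

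Islands found in a single line were shorter and had lower median folds than islands that met both other lines. Islands without a base of overlap with another line numbered 2288 in Pfeiffer, 2824 in WSU-DLCL2 and 4478 in KARPAS-422, which is 10.8%, 12.2% and 16.2% of each list. Their median lengths were 13.5, 11.25 and 10.5 kb, against 25.5, 24 and 20.25 kb for islands that met an island of both other lines. Their median folds were 1.46, 1.48 and 1.49, against 1.63, 1.58 and 1.69. Islands of a single line held 5.13%, 5.48% and 8.62% of the covered bases. A longer island more easily overlaps another by 1 base, so part of the difference in length follows from the rule. No expected length was computed, and folds were not compared at equal length. An interval without an island in a list held too few reads to be called, not necessarily none. The numbers depend on the list used: with a fold of at least 2 in every list they were 694, 998 and 2857, a larger share of the fewer islands left (31.1%, 38.3% and 52.9%), and with equal numbers of islands per list the order turned, to 3111, 2980 and 2565.

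Of the 12 islands that ranked highest among those common to the 3 lines, 11 lay within 5 Mb of a chromosome end, a distance chosen after they were seen, and 5 were on chromosome 16. Of all islands of a line that met both other lines, 12.4%, 13.3% and 12.4% lay that near an end. Relative input around 10 of the 12 was under 0.85 in KARPAS-422 (median of the 12 0.769, against 0.981 in Pfeiffer and 0.953 in WSU-DLCL2), which goes with its higher folds there. The first, on chromosome 16 from 1287751 to 1288500, had a fold of 6.58 in Pfeiffer (95% interval 3.49 to 13.7), 3.07 in WSU-DLCL2 (1.83 to 5.38) and 21.3 in KARPAS-422 (5.67 to 179). It held 11, 19 and 2 input reads, so its size was poorly determined. An island on chromosome 1, from 2458501 to 2477250 in every line, had folds of 2.93 (2.51 to 3.43), 3.23 (2.77 to 3.77) and 4.01 (3.28 to 4.95). On chromosome 14 the islands at 106131751 to 106136250 in Pfeiffer, 106125001 to 106135500 in WSU-DLCL2 and 106124251 to 106137000 in KARPAS-422 had folds of 3.65, 3.40 and 4.49. The remaining islands of this set had folds from 2.66 in Pfeiffer, 2.63 in WSU-DLCL2 and 3.49 in KARPAS-422 upward. These intervals cover counting error only, since amplified reads without molecular identifiers are not independent molecules. Nor do they allow for the choice of these islands by fold, which tends to favour folds that are too high.

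The strongest islands of a single line, with at least 50 H3K27me3 reads and no island of another line within 10 kb, were all under 15 kb. In Pfeiffer the first lay on chromosome 6 from 164435251 to 164437500 (fold 3.56, 95% interval 2.00 to 6.74), and the longest on chromosome 11 from 618001 to 631500 (fold 2.69, 2.18 to 3.34). In WSU-DLCL2 the first lay on chromosome 21 from 37687501 to 37692000 (fold 3.32, 2.11 to 5.41), and the best counted on chromosome 17 from 4853251 to 4860000 (fold 3.04, 2.32 to 4.03), where the relative input was 0.510 in Pfeiffer, 0.924 in WSU-DLCL2 and 0.881 in KARPAS-422. In KARPAS-422 the first lay on chromosome 16 from 4416751 to 4421250 (fold 5.71, 3.60 to 9.57). All named islands were chosen by fold, so their folds tend to be too high, and the intervals do not allow for this. Among islands of a pair of lines, WSU-DLCL2 and KARPAS-422 shared chromosome 16 from 67552501 to 67576500, with folds of 2.71 (2.38 to 3.10) and 3.07 (2.59 to 3.66), without an island of Pfeiffer within 10 kb. Relative input around it was 1.40 in Pfeiffer, 0.972 in WSU-DLCL2 and 0.937 in KARPAS-422. Pfeiffer and WSU-DLCL2 shared chromosome 19 from 1231501, with folds of 2.78 (2.14 to 3.64) and 2.94 (2.29 to 3.82), where the relative input was 0.868, 0.814 and 0.682 in the 3 lines. At the same input KARPAS-422 had an island nearby, from 1098001 to 1103250, with a fold of 4.65. Pfeiffer and KARPAS-422 shared chromosome 19 from 41317501, with folds of 3.95 (2.74 to 5.83) and 2.82 (1.96 to 4.16).

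The covered share of most chromosomes was alike in the 3 lines, and 6 of 22 chromosomes differed by at least 5 percentage points. Pfeiffer was highest on chromosome 5 (31.6%, against 20.2% in WSU-DLCL2 and 20.1% in KARPAS-422) and on chromosome 16 (42.8%, against 27.5% and 32.4%). KARPAS-422 was highest on chromosome 14 (36.9%, against 22.9% in Pfeiffer and 22.1% in WSU-DLCL2) and on chromosome 20 (51.4%, against 42.3% and 39.0%). WSU-DLCL2 was highest on chromosome 7 (27.2%, against 22.1% and 21.8%) and on chromosome 8 (30.1%, against 22.2% and 22.5%). On each of these chromosomes the line with the largest covered share also had raised input reads per kb. Relative to the median chromosome of the line, input was 1.42 and 1.46 in Pfeiffer on chromosomes 5 and 16, 1.41 and 1.22 in KARPAS-422 on chromosomes 14 and 20, and 1.22 and 1.37 in WSU-DLCL2 on chromosomes 7 and 8. Input was also raised in Pfeiffer on chromosomes 8 (1.38) and 17 (1.40) and in KARPAS-422 on chromosome 11 (1.43), where these lines had the smallest covered share of the 3 (22.2%, 38.5% and 25.9%). Each of these chromosomes also held a long block of low input in that line (0.572, 0.530 and 0.552). Islands covered only 2.98%, 5.52% and 5.56% of these blocks. A chromosome's input per kb of islands therefore reflects such blocks little. Covered share rose with gene density across the 22 autosomes in each line. Pearson's r was 0.60, 0.61 and 0.52 and Spearman's rho 0.71, 0.74 and 0.68, with two-sided permutation p-values adjusted over 6 tests (3 lines and both coefficients) of 0.002, 0.0017 and 0.025 for r and 0.0012, 0.0009 and 0.0014 for rho (0.0017, 0.0011 and 0.025, and 0.00041, 0.00015 and 0.00071, unadjusted). Without chromosomes 19 and 17, the farthest from the median density, r was 0.73, 0.73 and 0.61. Chromosomes within a line are not replicates. Covered share and gene density were divided by the same chromosome length, which includes stretches without an island in any line. Such a shared divisor can add to the relation.

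**Figure D1:**
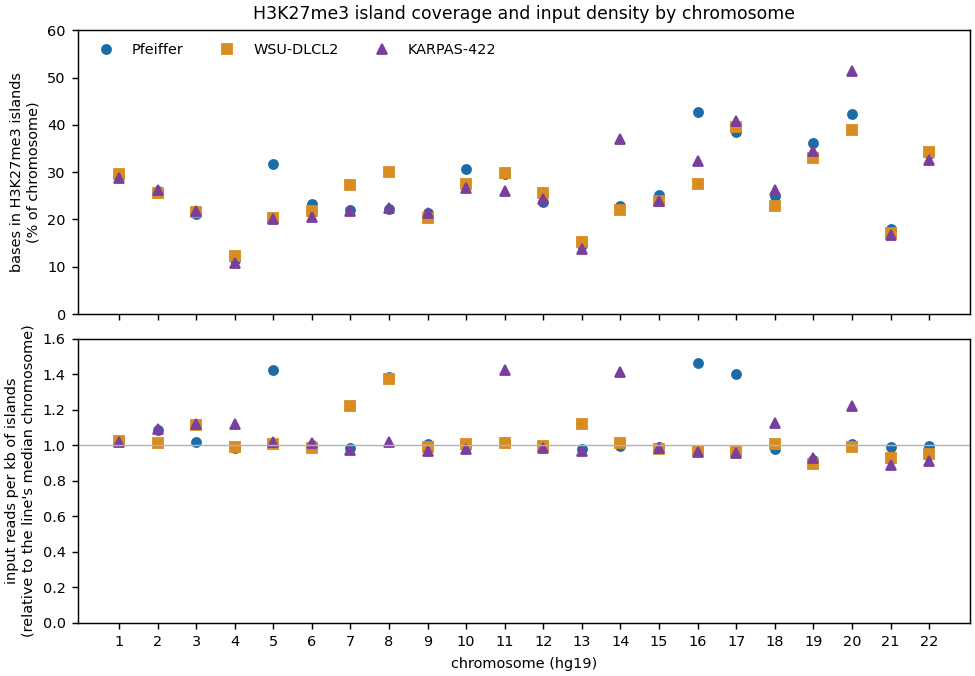
Share of each autosome in H3K27me3 islands (upper axis, percent) and input reads per kb of islands relative to the line's median chromosome (lower axis), with 1 point per line and chromosome and no replicates. Chromosomes 5 and 16 stand out in Pfeiffer, 14 and 20 in KARPAS-422 in both panels.

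Within chromosomes many of the large differences between lines lay in long blocks, though some lay in bins of balanced input (below). Runs of at least 5 bins of 1 Mb with a relative input of 0.75 or less numbered 3 in Pfeiffer, 2 in WSU-DLCL2 and 2 in KARPAS-422, and in 5 of these 7 the line with low input had the smallest covered share. In the others KARPAS-422 was lower still. On chromosome 4 from 183000001 to 188000000 Pfeiffer had 0.960% covered, WSU-DLCL2 32.0% and KARPAS-422 0.165%, too little to measure its input. On chromosome 10 from 85000001 to 90000000 WSU-DLCL2 had 6.60%, Pfeiffer 27.9% and KARPAS-422 2.13%, at inputs of 0.634, 1.02 and 0.540. On chromosome 8 from 5000001 to 44000000 islands covered 2.98% in Pfeiffer, 42.5% in WSU-DLCL2 and 27.6% in KARPAS-422, with median relative inputs of 0.572, 1.41 and 0.962. From 131000001 to 137000000 on the same chromosome WSU-DLCL2 had 3.31% covered at an input of 0.604, against 59.7% in Pfeiffer and 50.7% in KARPAS-422. On chromosome 17 from 1 to 18000000 Pfeiffer had 5.52% covered at an input of 0.530, against 35.8% and 42.98%. KARPAS-422 had 5.56% covered on chromosome 11 from 114000001 to 134000000 at an input of 0.552, against 51.4% and 48.9%. On chromosome 10 from 86000001 to 99000000 it had 1.18% at an input of 0.536, against 29.7% in Pfeiffer and 23.996% in WSU-DLCL2. The islands left in these blocks had high folds, with medians of 2.38 and 2.501 in Pfeiffer on chromosomes 8 and 17 and 2.67 and 2.70 in KARPAS-422 on chromosomes 11 and 10. On chromosome 11 from 81000001 to 114000000 KARPAS-422 had an input of 2.39 and 28.6% covered, against 15.3% and 16.7%. Its islands there had a median fold of 1.22 and a median length of 61.5 kb, against 1.44 and 19.5 kb in Pfeiffer. The last bins of this run were opposite: from 112000001 to 113000000 KARPAS-422 had 0.676% covered, against 63.7% and 59.8%, and from 113000001 to 114000000 4.43%, against 69.3% and 73.9%. Their pooled inputs of 4.37 and 5.05 include islands outside the bins, so they do not measure input in the bins themselves. The limits of input that define these runs were set after the data had been seen.

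**Figure D2:**
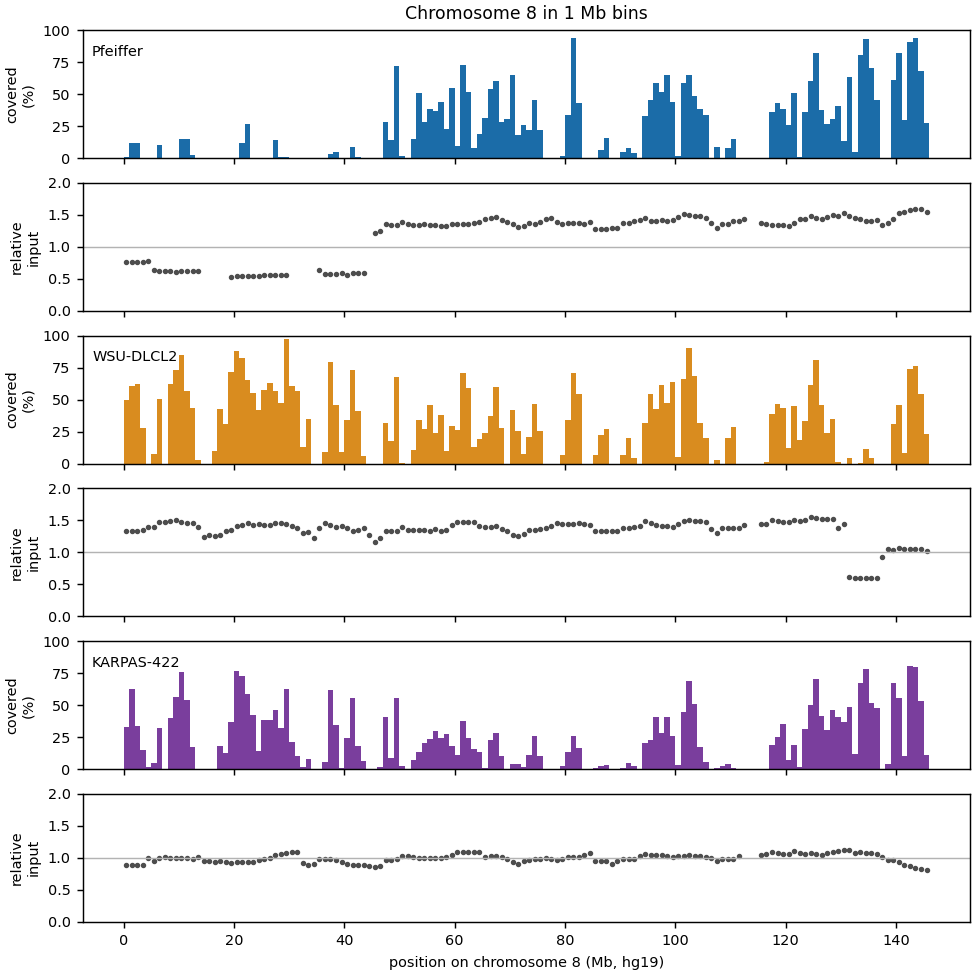
Covered share (bars, percent) and input reads per kb of islands relative to the autosomal median of the line (points) in 1 Mb bins along chromosome 8, for the 3 lines. Pfeiffer has few islands up to 44 Mb (2.98% covered from 5 Mb on) and WSU-DLCL2 from 131 to 137 Mb (3.31%), where the input of that line is low.

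Over all autosomes, 67 of 2871 bins of 1 Mb differed by at least 40 percentage points between Pfeiffer and WSU-DLCL2, 93 between Pfeiffer and KARPAS-422 and 81 between WSU-DLCL2 and KARPAS-422. Where both other lines had balanced input, between 0.85 and 1.15 of their medians, a line with an input of 0.75 or less had few bases in called islands. Its mean covered share was 5.87% in 14 such bins of Pfeiffer, 8.63% in 5 of WSU-DLCL2 and 7.48% in 28 of KARPAS-422, against 39.0%, 38.6% and 44.0% in the other lines. With an input of 1.3 or more the covered share was 42.9% against 29.95% in Pfeiffer (244 bins), 37.9% against 22.997% in WSU-DLCL2 (59 bins) and 40.1% against 24.0% in KARPAS-422 (166 bins). In the 1527 bins with balanced input in all 3 lines, 8, 12 and 18 differences of at least 40 points remained for the pairs in the same order. Spearman's rho of covered share across bins, which are not replicates, was 0.88, 0.86 and 0.86 over all bins and 0.91, 0.91 and 0.88 over the balanced bins.

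**Figure D3:**
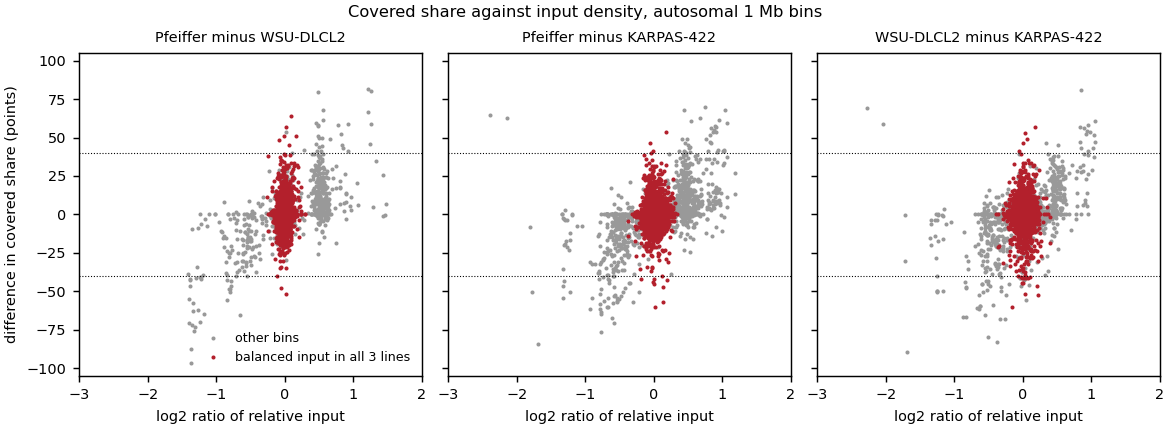
Difference in covered share (percentage points) against the log2 ratio of relative input for each pair of lines, with 1 point per autosomal 1 Mb bin and dotted lines at 40 points. Bins with balanced input in all 3 lines are red, and 8, 12 and 18 of them lie beyond the dotted lines.

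Among the balanced bins, several regions differed in covered share. On chromosome 2 from 100000001 to 101000000 islands covered 68.7% in WSU-DLCL2, 17.2% in Pfeiffer and 22.2% in KARPAS-422. On chromosome 3 from 54000001 to 55000000 KARPAS-422 had 73.5% covered, Pfeiffer 13.0% and WSU-DLCL2 28.7%. On chromosome 19 from 31000001 to 32000000 WSU-DLCL2 had 28.8%, Pfeiffer 73.9% and KARPAS-422 80.9%. On chromosome 6 from 168000001 to 169000000 WSU-DLCL2 had 25.4%, Pfeiffer 76.1% and KARPAS-422 67.1%. Input in the bin could be read only in the islands each line had there, not in the stretches where the lower line had none. In those islands the input of the lower line was 1.12 and 1.15 times that of WSU-DLCL2 on chromosome 2. The corresponding ratios were 1.03 and 0.931 on chromosome 3, 0.974 and 0.958 on chromosome 19, and 0.875 and 1.02 on chromosome 6. These bins were picked after their values were seen, and no replicate shows how often a second library would give the same islands.

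**Figure D4:**
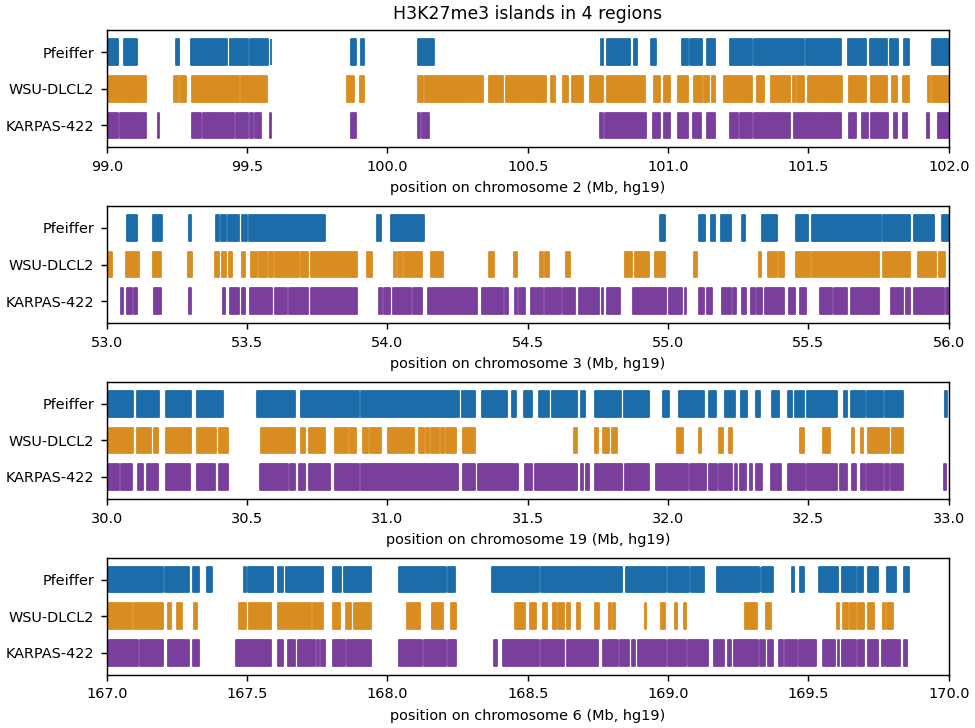
Islands of the 3 lines (boxes) along 3 Mb of chromosomes 2, 3, 19 and 6, to scale in hg19. WSU-DLCL2 has more of the bin from 100 to 101 Mb covered on chromosome 2 (68.7%), and KARPAS-422 more of 54 to 55 Mb on chromosome 3 (73.5%).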

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

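The signal on chromosome X lay outside the comparisons. The tests were chosen after the covered shares of X had been seen; the bound from autosomal ratios was set before those ratios were computed, and the bins of matched coverage were added later. Islands covered 0.644% of chromosome X in Pfeiffer, 0.962% in WSU-DLCL2 and 9.32% in KARPAS-422. Relative input on X was 0.714, 0.648 and 0.973, so a lower DNA copy number could account for the difference. These inputs were read in 60, 114 and 883 islands, with median folds of 2.13, 2.22 and 1.55. Those of Pfeiffer and WSU-DLCL2 thus rest on few islands of high fold, which can make input look low. In Pfeiffer the covered share was 0.0692 times that of KARPAS-422. That lies below the lowest ratio in autosomal blocks of low input (0.115), the bound that was to count as evidence against copy number. The bound was a poor one: it rests on 2 chromosomes where KARPAS-422 had 37.1% covered, and in 6 bins where KARPAS-422 had 2 to 20% covered the ratio was 0.0575. In WSU-DLCL2 the ratio was 0.103, with 0.0653 on the 1 chromosome that could be used and 0.126 over all 11 autosomal bins of low input, so X lay between them. Copy number and a difference in the mark cannot be told apart on X with so few chromosomes to compare. No biological explanation was tested.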

How the results depend on the processing

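Of 100 values under other settings, 52 stayed within their limits and 48 moved beyond them. The limit was a factor of 1.5 for counts and covered lengths. For indices and shares it was the 95% binomial interval, which is narrow, so small shifts pass it. The limits apply to single values, not to the order of the lines. The settings of balanced bins, of short shifts and of lists without dense input were chosen after seeing the data. The planned results on promoters and gene lists were not run, with all their alternatives, because no hg19 annotation was used here. No paired analysis was possible because each line had 1 library. The lead of Pfeiffer and WSU-DLCL2 in overlap was lost at a fold of at least 2 and was 0.5418 against 0.5417 at a false discovery rate of 1e-10; the cause was not tested. Equal covered length and lists without dense input moved none of these values beyond their limits.

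At a false discovery rate of 1e-10, islands numbered 13970, 14095 and 16895 in Pfeiffer, WSU-DLCL2 and KARPAS-422, and those of KARPAS-422 alone 2704. Jaccard indices were 0.542 (Pfeiffer and WSU-DLCL2), 0.542 (Pfeiffer and KARPAS-422) and 0.518 (WSU-DLCL2 and KARPAS-422), and 38.1% of covered bases were in all 3 lines. With a fold of at least 2, islands numbered 2233, 2603 and 5403, covering 104, 98.2 and 179 Mb. Those of at least 50 kb numbered 613, 620 and 1034 and those of 1 line alone 694, 998 and 2857 (31.1%, 38.3% and 52.9% of the islands left). The indices were 0.283, 0.345 and 0.278, and 15.1% of bases were in all 3 lines. Fewer islands are left by construction under both settings. With equal numbers of islands the indices were 0.572, 0.545 and 0.540, the share in all 3 lines was 40.1%, and islands of 1 line alone were 3111, 2980 and 2565, so that the order of the lines turned. With chromosome X, covered lengths were 738.7, 715.1 and 726.3 Mb, so WSU-DLCL2 no longer exceeded KARPAS-422. Pfeiffer and KARPAS-422 had 0.547, WSU-DLCL2 and KARPAS-422 0.546, and 40.6% of bases were in all 3 lines. In balanced bins only, the indices were 0.590, 0.579 and 0.568, and 43.4% of bases were in all 3 lines. There 12.7% of islands of WSU-DLCL2 were its alone, and islands of at least 50 kb were 14.8%, 13.9% and 9.33% of each list (17.5%, 15.8% and 11.1% over all autosomes). At a minimum of 100 kb, long islands numbered 1240, 1101 and 876. With islands under 5 kb apart joined, those of at least 50 kb numbered 4130, 4305 and 3884, so the lead of Pfeiffer was lost. Islands of Pfeiffer alone were 3456 where 50% of the island had to be overlapped, and 1510 with no other island within 10 kb. Shifts of 0.5 to 2 Mb raised the median index of shifted lists to 0.232, 0.235 and 0.229.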

Other observations

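The tests of bins and of library size were chosen after the results were seen; for island length in balanced bins the bins were also chosen after, but the bound was written before that ratio was computed. Islands with far more input reads than usual marked a few places. KARPAS-422 had 72919 H3K27me3 and 37342 input reads in its island on chromosome 11 from 110574001 to 111478500. Pfeiffer had 4.17 times its median input per kb on chromosome 2 from 60084001 to 60262500. Near 91.8 Mb of chromosome 2 an island had dense input in every line (7.39, 3.53 and 3.43 times the median in Pfeiffer, WSU-DLCL2 and KARPAS-422). In runs of at least 5 bins of raised input (1.3 or more), the line had the largest covered share of the 3 in 19 of 20 runs of Pfeiffer, 9 of 11 of WSU-DLCL2 and 12 of 14 of KARPAS-422. These counts include near ties and runs of raised input in other lines too. On chromosome 1 from 142000001 to 147000000 inputs were 1.61, 1.61 and 1.74, with 9.17%, 9.14% and 7.80% covered. On chromosome 2 from 58000001 to 66000000 Pfeiffer had 34.8% covered and KARPAS-422 34.7%.

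Large differences in covered share between lines may come mostly from DNA copy number, which changes the reads available to call an island. Input was read only in islands called against that same input, so input and covered share are not independent measures. Where a line has few islands, those called can be the ones with little input. How far this acts was not tested. Input was higher, by a log2 of at least 0.2, in the line with the larger covered share in 78.4% of differences of at least 40 points between a pair of lines (182 of 232 with a measured input; 3 per pair had none and are left out). Per pair this was 85.9% for Pfeiffer and WSU-DLCL2, 84.4% for Pfeiffer and KARPAS-422 and 65.4% for WSU-DLCL2 and KARPAS-422, and input was opposite in 0, 2 and 4. The same held in 11.4% of pair differences under 10 points. Bins of equal covered share, among them bins without an island in either line, could not meet this condition and lower that percent. The pair differences are not independent. Neighbouring bins share pooled input, a bin can count in more than 1 pair, and many bins lie in the same blocks. For example, 25 of the 33 bins with WSU-DLCL2 above Pfeiffer lay on chromosome 8. The 38 differences in balanced bins were weighed apart. In 27 of them input could be read in the islands that the lower line still had in the bin. The ratio of the lower to the higher line was between 0.85 and 1.15 in 23 of these, under 0.85 in 3, and under 1 in 20 (median 0.927). Such islands do not show a loss of DNA in a stretch without islands, so the longest such stretch of the lower line was left out. In 10 of 27 the rest of the bin still differed by at least 40 points at a balanced ratio, with a 95% interval above 0.75. All 23 balanced ratios met this limit of the interval, so it left out none. The 10 are pair differences, and bins on chromosomes 6 and 22 count in 2 pairs each. In these 10 a single loss inside that stretch is argued against as the whole cause, though several short losses are not. Both differences of WSU-DLCL2 on chromosome 6 from 168000001 are among them (54.9 and 46.8 points outside). On chromosome 2 from 100000001 only 13.2 and -2.31 points were left, and for Pfeiffer on chromosome 3 from 54000001 -0.935. On chromosome 2 both lower lines lacked islands over nearly the same stretch, which held islands in WSU-DLCL2. It ran from 100164750 to 100760251 in Pfeiffer and from 100146750 to 100757251 in KARPAS-422. Leaving out such a stretch cannot show a mark present only in the higher line. In the other 11 of the 38 a line had too few islands to read input at all. Over the balanced bins as a set, a short loss of DNA and a loss or gain of the mark cannot be told apart. On chromosome 10 from 99000001 to 100000000, which is among the 11, the 18 kb of islands in KARPAS-422 had an input of 0.526, and the run of low input in that line ends at 99000000.

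More and shorter islands in KARPAS-422 than in Pfeiffer could come from a smaller H3K27me3 library or from copy number. The H3K27me3 library of KARPAS-422, estimated from input reads per kb and the library ratio, was 0.990 times that of Pfeiffer on the median chromosome (quartiles 0.918 and 1.00), which argues against a smaller library. In balanced bins its median island was still 0.769 times as long, which argues against copy number as the whole cause. Differences in immunoprecipitation or in fragment size were not tested and stay open, as does a difference between the lines themselves.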
